A study of Homo sapiens with 9 samples.

How the data were processed

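RNA sequencing libraries came from SUM159PT, an established triple-negative breast cancer cell line, in 3 groups of 3 libraries each. The groups were control cells (NC) and cells in which PTK7, a receptor-like pseudokinase of the Wnt and planar polarity pathways, had been edited with either of 2 guide RNAs (KO1 and KO2). Per the labels' protocols, Cas9 and the guides were delivered with lentivirus, cells were selected with puromycin, a monoclonal line was grown, and poly(A) RNA was copied with random primers and sequenced on an Illumina HiSeq instrument. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples. If each knockout group is its own monoclonal line, clone and edit differ together in KO1 and KO2 against NC and cannot be told apart. Genes, gene lists and chromosome regions described below as changed in a knockout are therefore differences between groups of libraries. They are not shown to be effects of editing PTK7.

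The submitters' processing notes list HISAT2 2.0.1, HTSeq 0.6.1 and the genome build hg19, without saying how they were combined. The strand setting and the annotation release are not given in the sources used here. The authors deposited 2 tables, each holding whole-number counts and FPKM (fragments per kilobase of exon, scaled to the library total) for 61806 genes in 6 libraries. Per the file headers, the first table holds NC and KO1 and the second holds NC and KO2, whose columns carry another knockout number than the labels and were matched through the sample descriptions. The deposited FPKM equalled counts divided by exonic length and by the library total to within 0.005 in both tables. Gene coordinates in both tables matched GRCh38 and not the hg19 of the notes: of 58254 genes shared with GENCODE v29, 80.6% had the same start and 98.7% a start within 10 kb. Coordinates below are therefore GRCh38, and the build used for alignment stays unknown.

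The 3 NC libraries stand in both tables with different counts. Between 71.7% and 73.4% of genes had the same count in both, and the second table held 5.23%, 5.56% and 5.45% more counts for NC replicates 1, 2 and 3. Of 16548 genes with at least 30 NC counts in either table, 688 differed by over 1.2-fold between tables. Each knockout was therefore compared with the NC counts of its own table. Total counts per library ran from 13151026 to 15888406 in the first table and from 13838712 to 17273328 in the second.

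Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and groups were compared with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment within a comparison and calls at an adjusted p under 0.05. Gene levels are in CPM, counts scaled by library total and TMM factor, given as mean ± SD with n = 3. The groups, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. That plan assumed FPKM tables and named limma-trend on log2(FPKM + 1), with edgeR to be used if the tables held counts, which they did. The test of KO2 against KO1 was added after the data were seen. It used library columns from both tables and was limited to 14519 of 16090 genes with at least 30 NC counts in each table and NC totals within 1.1-fold.

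Numbers shared between replicates were checked as a pairing: deviations of KO1 and NC libraries of the same number correlated across genes at 0.29, 0.30 and 0.32, and those of KO2 and NC at 0.19, 0.09 and 0.42, beside values of −0.39 to 0.23 for libraries of different number. Across genes, which are not independent replicates, this pointed to a pairing for KO1 and not for KO2. A fit with the replicate number as a block was run for both.

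The gene lists, 37 in all, covered DNA repair, immune signalling, Wnt signalling, cell state, metabolism, stress and markers of other cell types. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and adjusted over the lists of a comparison. The same test with an estimated correlation stands beside it, and the fry test was run on every list, with its values given for some lists of KO2. The results of 1 list called in KO1, counted below among the lists, and of 1 gene are not reported here. fry asks whether the members of a list move one way and does not compare them with other genes.

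Named genes followed a rule. PTK7, PRKDC, XRCC5 and XRCC6 were always given. Genes called in both knockouts in one direction, with no overlap between NC and knockout libraries, supplied up to 12 higher and 12 lower genes by the smaller of their absolute fold changes. Each comparison supplied the 5 higher and 5 lower called genes with the largest fold change, a symbol and no overlap, and each list up to 4 members with the smallest p. With all libraries the rule named 0 genes called in both knockouts and 0 genes for KO1, because edgeR called 0 genes in KO1. The rule was therefore also applied to fits without the library labelled NC replicate 1, a choice made after the data were seen. Not every list member that the rule named is given in the text. A few genes outside the rule are marked as such.

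Folds against a group with 0 counts are lower bounds against a floor of 3 counts over the group. For genes with 1 to 3 counts in a group the ratio is given with its 95% counting interval. Intervals and floors cover counting error only.

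The test was tried on simulated data in which 100 well-expressed genes were changed 4-fold and 100 others 16-fold in counts drawn with the spread of each comparison. For KO1 it recovered 92 and 100 of them with 15 false calls among 16240 genes, and for KO2 86 and 100 with 10 false calls among 16019. The simulated libraries were independent, with no control library beside a knockout and no libraries that nearly repeat each other. The real data hold both, as given below, so these rates check the code and do not carry over to the real comparisons.

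Alternatives covered DESeq2 1.42.0, voom, limma-trend on FPKM with other pseudocounts, filters and scalings, other filters on counts, stricter thresholds, blocks, and leaving out each library in turn. Alignment could not be repeated, since no reads were at hand.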

Results

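Gene expression was measured by RNA sequencing in 9 libraries of SUM159PT cells, 3 each of NC, KO1 and KO2, to ask how the transcriptome changed when PTK7 was edited; the series title places the question in DNA repair, DNA-PK and immune evasion. In the first table, total counts were 15304554, 13723752 and 13779410 for KO1 replicates 1 to 3 and 13151026, 15576836 and 15888406 for NC. In the second table, they were 16415677, 16658033 and 17273328 for KO2 and 13838712, 16442398 and 16754776 for NC. The library labelled NC replicate 1 lay apart from the other NC libraries and beside KO1 on the first principal component of the first table, which held 47.8% of the variance. In the second table KO2 replicates 1 and 2 lay together, and KO2 replicate 3 lay between them and NC on the first component, with 52.6% of the variance.

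**Figure D1:**
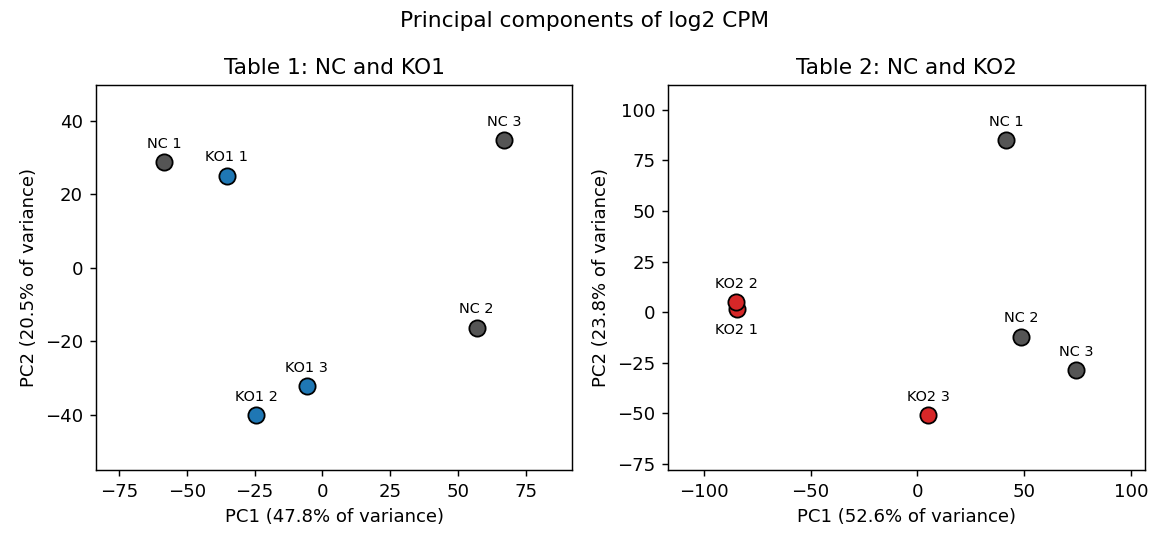
Principal components 1 and 2 of log2 CPM for the libraries of each table, 1 point per library, coloured by group, with the percent of variance on the axes. On component 1 of the first table, NC replicate 1 stood at −58.4, beside the KO1 libraries and away from NC replicates 2 and 3 at 56.9 and 67.0.

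PTK7 (ENSG00000112655, chromosome 6, 43076307 to 43161719 in GRCh38) stood at 24.3 ± 7.47 CPM (SD, n = 3) in KO1 and 117 ± 84.2 CPM in NC of the same table. In KO2 it stood at 74.7 ± 22.6 CPM beside 110 ± 78.7 CPM in NC. The NC spread came from the library labelled NC replicate 1, which held 331 PTK7 counts in the first table, in the range of the 269, 336 and 419 counts of KO1, while NC replicates 2 and 3 held 2822 and 2129. The log2 fold change was −2.27 (SE 0.63) in KO1, with an adjusted p of 1.00 by edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, and all 3 KO1 libraries were below NC replicates 2 and 3. Without the library labelled NC replicate 1 it fell by 2.74 on the log2 scale, with an adjusted p of 4.05e-04; over the alternatives of the same edgeR and other fits the adjusted p ran from 1.66e-13 to 1. In KO2 the log2 fold change was −0.56 (SE 0.63; adjusted p = 0.612, range over alternatives 0.0177 to 0.962), and all 3 KO2 libraries were below NC replicates 2 and 3 and above NC replicate 1, which stood at 22.2 CPM in that table. Leaving out 1 library moved this value to −1.04 without NC replicate 1, −0.08 without NC replicate 2 and −0.33 without KO2 replicate 3. A guide that shifts the reading frame need not lower the mRNA, so these levels measure transcript and not protein.

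**Figure D2:**
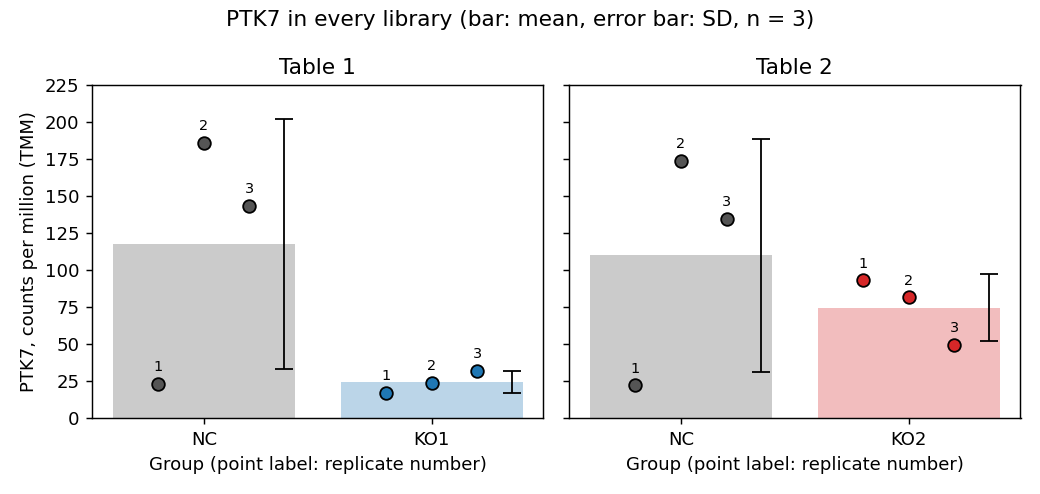
PTK7 level in CPM for each library of both tables, with a bar for each group mean, a line for its SD and a point per library. NC replicate 1 stood at 23.4 CPM in the first table, within the KO1 range, while NC replicates 2 and 3 stood at 186 and 143 CPM.

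In KO1 against NC, with all 6 libraries, edgeR called 0 of 16240 genes at an adjusted p under 0.05, and 676 genes had an unadjusted p under 0.05. DESeq2 called 67 genes, 12 higher and 55 lower, and voom and limma-trend called 0. The low count rested on 1 library: without the library labelled NC replicate 1, edgeR called 581 of 16969 genes, 277 higher and 304 lower, while leaving out any other library gave 0. Without replicate 1 of both groups and with the replicate number as a block, it called 1328 genes, 665 higher and 663 lower. That fit was also chosen after the data were seen and left few libraries for its block and group terms. Its larger count is therefore no stronger evidence of a change in KO1. The KO1 genes below come from the unpaired fit without the library labelled NC replicate 1, which was chosen after the data were seen.

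Without that library, KRT14, basal keratin 14 (ENSG00000186847, chromosome 17), was called lower in KO1. It had 0 counts in all 3 KO1 libraries, at least 269-fold lower than in NC replicates 2 and 3 at 30.6 and 8.52 CPM. NC replicate 1 was also at 0. The xylosyltransferase XYLT1, which starts glycosaminoglycan chains on proteoglycans, was at least 108-fold lower, the neuropeptide precursor GAL at least 57.1-fold, the metallothionein MT1E at least 48.1-fold and the pseudogene CXADRP1 at least 44.9-fold. All of them were also at 0 in the library left out, so they set NC replicates 2 and 3 apart from KO1 and from that library alike. Among genes that rose, CHRNA7, a nicotinic acetylcholine receptor subunit, stood at 16.9 ± 1.85 CPM in KO1 against 1 count in NC replicates 2 and 3, a ratio of 534 (95% counting interval 95.6 to 21135), and at 26.4 CPM in the library left out. OLR1, a lectin-like scavenger receptor, was at least 42.6-fold higher, with 2.54 CPM in the library left out. CNBD1 was at least 22.3-fold higher, and the noncoding RNAs LINC02506 and LINC01060 at least 48.0-fold and 19.4-fold, with 2.47, 2.61 and 1.55 CPM of them in the library left out. LINC02506 is among the genes whose NC counts differed between the tables.

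Several fixed lists held genes that changed in KO1 in the fit without the library labelled NC replicate 1. Of 34 measured collagens and matrix genes, 7 fell and 0 rose (4 higher and 15 lower adjusted over the list alone). The basement membrane collagens COL4A1 and COL4A2 fell by 4.14 and 4.08 on the log2 scale, with all 3 KO1 libraries at or below 7.58 CPM for COL4A2 against 98.0 and 116 CPM in NC replicates 2 and 3. Of 27 chemokines and cytokines, 8 fell and 0 rose (3 higher and 11 lower adjusted over the list alone), among them CSF3, the granulocyte colony-stimulating factor, by 5.79, and the neutrophil chemokine CXCL1, by 4.38. Of 31 mesenchymal and EMT genes 6 fell (7 adjusted over the list alone), with the membrane protease MMP14 lower by a log2 fold change of −1.91. Of 19 epithelial genes 5 fell (8 adjusted over the list alone), with KRT17 at −5.16. The library left out stood near KO1 here too, at 7.85 CPM for COL4A1, 12.6 for COL4A2, 3.75 for CSF3, 0.0708 for CXCL1, 38.0 for MMP14 and 0.212 for KRT17. Of 33 Wnt receptor, ligand and polarity genes 4 fell and 0 rose (4 lower adjusted over the list alone): PTK7, the formin DAAM2, and the ligands WNT7B (−1.81; 3.33 CPM in the library left out) and WNT5B (−3.17), which were named after their values were seen. The Wnt list as a whole did not pass (adjusted p = 0.169, median 0.01). Other lists that did not pass also held called genes, and not all are given here. Among them, 3 NF-kappaB targets and 3 YAP and TEAD targets fell, 2 metallothionein and NRF2 genes rose and 2 fell, and 2 checkpoint genes and 2 Wnt/beta-catenin targets rose and 1 of each fell.

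In the same fit, camera gave adjusted p-values of 7.93e-10 for matrix, 5.37e-07 for chemokines, 7.66e-06 for mesenchymal and 4.14e-06 for epithelial genes, all lower. With an estimated correlation these were adjusted p = 0.846 for matrix and adjusted p = 0.523 for the other lists. Over the alternatives their highest adjusted p was 0.208, 0.739, 0.399 and 0.901. Hypoxia and glycolysis genes (5.94e-07; 2 of 37 members fell, 3 adjusted over the list alone) and cytosolic ribosomal proteins (7.38e-03; 0 of 59 members passed) were also lower, each with an adjusted p = 0.988 with an estimated correlation. With all libraries neither passed (0.439 and 0.593), and over the alternatives their highest adjusted p was 0.983 and 0.865. The hypoxia list was called in the opposite direction without NC replicate 2 (0.0393, 26 of 37 members positive, median 0.13). Medians without NC replicate 1 were −0.62, −0.38, −0.33, −0.31, −0.44 and −0.20 in the order named.

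With all 6 libraries, camera called 6 lists in KO1, in none of which a member passed the edgeR test over all genes, while adjusted over the list alone 2 matrix genes and 1 chemokine passed as lower and 0 in the other lists called. Each call ended without at least 1 library. Interferon response genes were higher (adjusted p = 2.40e-04, median log2 0.17, 33 of 38 members positive), and the call ended without KO1 replicate 2 (0.0671) or NC replicate 1 (0.123). Matrix genes were lower (2.40e-04), and the call ended without KO1 replicate 1 (0.0803) or NC replicate 2 (0.208). Mesenchymal genes were lower (0.0101), which ended without KO1 replicate 1 (0.0993), NC replicate 2 (0.399) or NC replicate 3 (0.0559), and on FPKM by limma-trend with TMM (0.0540) or a pseudocount of 0.1 (0.0788). Oxidative phosphorylation genes were higher (0.0109), which ended without KO1 replicate 3 (0.842) or NC replicate 1 (0.966). Chemokines were lower (0.0474), which ended without KO1 replicate 1 (0.0803), NC replicate 2 (0.739) or NC replicate 3 (0.122), with the replicate block (0.259), and in both FPKM fits (0.319 and 0.354). Metallothioneins and NRF2 targets were called only with that block (0.0188, against 0.1003 without). Without the block, camera with an estimated correlation gave this list an adjusted p of 0.927. With an estimated correlation all 6 lists had an adjusted p = 0.927. End-joining and recombination genes did not pass (adjusted p = 0.911 and 0.593).

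In KO2 against NC, edgeR called 218 of 16019 genes, 101 higher and 117 lower, and 3795 genes had an unadjusted p under 0.05. If KO2 is a monoclonal line, these calls cannot tell a difference of that clone from an effect of the edit. The erythrocyte membrane protein 4.1-like gene EPB41L3 (ENSG00000082397, chromosome 18, 5392381 to 5630700) was nearly silent in KO2, with 1 count over the group against 37.6 ± 7.98 CPM in NC, a ratio of 1995 (interval 358 to 78849; adjusted p = 2.78e-03). LINC00960 (at least 82.8-fold), LINC02864 (45.3-fold), the zinc finger gene ZNF717 (43.2-fold) and PLCB1, a phospholipase C (39.2-fold), had 0 counts in KO2; LINC00960 and ZNF717 overlap on chromosome 3. SUCNR1, the succinate receptor (ENSG00000198829, chromosome 3), rose to 21.0 ± 4.34 CPM from 0.502 ± 0.232 (log2 5.36, SE 0.44, adjusted p = 0.0162). The carboxypeptidase gene CPVL rose by 5.49 on the log2 scale (SE 0.82, adjusted p = 0.0330). HOXB3, a homeobox gene with 0 counts in NC, was at least 22.7-fold higher. WT1, a zinc finger transcription factor, had a ratio of 121 (21.3 to 4797) and FSTL5 of 47.6 (8.18 to 1918), each against 1 count in NC.

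The KO2 count moved with single libraries. It was 3498 without KO2 replicate 3, and 2, 1, 7 and 1 without KO2 replicate 1, KO2 replicate 2, NC replicate 2 and NC replicate 3, while 226 genes were called without the library labelled NC replicate 1, 106 of them among the 218. All 218 were among the 3498, but the KO2 group of that fit held only KO2 replicates 1 and 2. These nearly repeat each other, as given next, so the overlap does not measure how well the calls held. KO2 replicates 1 and 2 differed by little more than counting noise, with a chi-square over degrees of freedom of 2.77 between them against 33.2 to 265 for the other pairs of libraries. The labels do not say whether they are repeats of 1 culture or library. With the 2 summed as 1 library, a fit chosen after the data were seen, edgeR called 1 gene in place of 218, with 2229 at an unadjusted p under 0.05. That gene was lower in KO2, so no gene named as higher in KO2 with all libraries was called in the summed fit. The gene lists were not tested in the summed fit, so the list results below count both libraries as separate. The split of higher and lower calls followed the scaling: library totals without TMM gave 55 higher and 116 lower, with the median of all genes at −0.19 in place of −0.05, and limma-trend with quantile normalization gave 67 higher and 47 lower.

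Immediate early genes, which respond within minutes to growth factors and stress, were higher in KO2 as a list by camera with the preset correlation (adjusted p = 3.12e-07; adjusted p = 0.249 with an estimated correlation). Of 23 measured, 5 rose over all genes (11 higher and 1 lower adjusted over the list alone) and 19 had a positive log2 fold change. JUN, a subunit of the AP-1 transcription factor, stood at 282 to 353 CPM in KO2 against 85.5 to 117 CPM in NC (log2 1.72), JUND rose by 1.69, ATF3, a stress-induced transcription factor, by 2.61, and the MAP kinase phosphatase DUSP1 by 3.13. The fifth called member, KLF6, rose by 2.01 and is named outside the rule. The heat shock list was higher (adjusted p = 0.0177; adjusted p = 0.590 with an estimated correlation) with 2 of 14 members called (4 adjusted over the list alone): the chaperones DNAJB1 (1.76) and HSPA1B (2.10). The heat shock call ended without the library labelled NC replicate 1 (0.205) and on FPKM by limma-trend with TMM (0.158) or a pseudocount of 0.1 (0.132). The fry test of movement in one direction gave 0.0189 for immediate early genes.

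Interferon response genes were higher in KO2 as a list by camera (adjusted p = 3.26e-06; adjusted p = 0.249 with an estimated correlation), with 34 of 38 members positive, a median log2 fold change of 0.78 and 3 members called over all genes. These 3 (8 adjusted over the list alone) were the ubiquitin-like modifier ISG15 (1.70; 54.8 to 59.2 CPM in KO2 against 11.6 to 20.4 in NC), the ISG15 ligase HERC5 (2.48) and the RNA sensor IFIH1 (1.23). IRF7 had a log2 fold change of 1.92 and did not pass (adjusted p = 0.0648). The MHC class I antigen presentation list was higher too (adjusted p = 1.29e-05; adjusted p = 0.546 with an estimated correlation). Of its 21 genes 20 were positive, with a median of 0.68, and 0 passed over all genes in edgeR's quasi-likelihood test, while 10 passed adjusted over the list alone. The peptide transporter TAP1 (1.29, adjusted p = 0.0642), HLA-C (1.35, 0.0645), HLA-B (1.28, 0.0791) and TAPBP (1.29, 0.0821) were higher than NC in each of 3 KO2 libraries; HLA-B stood at 985, 953 and 529 CPM in KO2 replicates 1, 2 and 3 against 266 to 382 in NC. The checkpoint list was higher (adjusted p = 1.29e-04; adjusted p = 0.442 with an estimated correlation), and of its 25 genes the T-cell costimulator TNFSF9 rose (3.17) and 8 members passed adjusted over the list alone, with CD70 at 2.401, CD276 at 1.201 and the NKG2D ligand ULBP2 at 1.22. The fry test gave 0.0189, 0.0932 and 0.0554 for the interferon, MHC class I and checkpoint lists.

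Cholesterol, G2 and M phase, matrix, mesenchymal and luminal lists were also higher in KO2 by camera with the preset correlation, with adjusted p-values of 1.71e-04, 4.58e-04, 6.56e-03, 5.47e-04 and 0.0377 in that order. None of these calls held with an estimated correlation (adjusted p = 0.590, 0.700, 0.688, 0.590 and 0.536). Of 24 cholesterol genes 0 passed in edgeR over all genes and 7 adjusted over the list alone (median 0.89): INSIG1 had a log2 fold change of 3.13, MSMO1 of 2.00 and STARD4 of 1.64. INSIG1 stood at 371 and 364 CPM in KO2 replicates 1 and 2 but 38.2 in KO2 replicate 3, within the NC range of 14.2 to 41.1. Of 34 G2 and M phase genes 29 were positive (median 0.47, 0 passed over all genes and 0 adjusted over the list alone), with the topoisomerase TOP2A at 0.85. The 37 S phase and replication genes went the other way, with 4 positive, a median of −0.40 and 0 called over all genes or over the list alone (adjusted p = 0.0563, lower, range over alternatives 2.24e-06 to 0.758; adjusted p = 0.773 with an estimated correlation). They passed without KO2 replicate 3 (2.24e-06), NC replicate 1 (0.0258) or NC replicate 2 (0.0195), with the replicate block (7.38e-04) and on FPKM with TMM (6.88e-03) or a pseudocount of 0.1 (0.0190). Of 31 matrix genes 1 rose, the microfibril gene FBN1 (2.70; 6 higher and 3 lower adjusted over the list alone). Of 30 mesenchymal genes 0 passed over all genes and 6 adjusted over the list alone, with SPARC at 2.11, MMP2 at 1.54 and MMP14 at 2.50. Markers of luminal breast cells had a median of 0.58 over 8 measured, 0 called. The G2 and M call ended without KO2 replicate 3 (0.111), matrix and mesenchymal without NC replicate 1 (0.705 and 0.192), and the luminal call without KO2 replicate 1 (0.0695), 2 (0.0989) or 3 (0.204) or NC replicate 1 (0.0922) or 2 (0.0629), and on FPKM with TMM (0.0599). The fry test gave 0.0189 for the luminal list.

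Homologous recombination genes were lower in KO2 as a list by camera with the preset correlation (adjusted p = 1.75e-03; adjusted p = 0.700 with an estimated correlation). Of 26 measured, 24 had a negative log2 fold change, with a median of −0.55, 0 passed over all genes in edgeR's quasi-likelihood test and 1 adjusted over the list alone. RBBP8, which starts DNA end resection, had a log2 fold change of −1.55 (adjusted p = 0.0508), BRCA2 of −1.19 (0.116), RAD54L of −0.74 (0.135) and PALB2 of −1.05 (0.159), each lower in 3 of 3 KO2 libraries than in any NC library. The 19 end-joining genes had a median of −0.24 and did not pass (adjusted p = 0.269, 0 members called, 0 adjusted over the list alone) except on FPKM with a pseudocount of 0.1 (0.0404; range 0.0404 to 0.534). The 15 Fanconi anaemia genes had a median of −0.37 (0.0563), which passed without KO2 replicate 3 (9.50e-03) or NC replicate 2 (0.0276), with the replicate block (0.0443) and on FPKM with TMM (0.0315) or a pseudocount of 0.1 (0.0294). The 25 base excision and mismatch repair genes had a median of −0.22 (0.0765, 0 called), which passed without KO2 replicate 3 (0.0170) or NC replicate 2 (0.0320), with the replicate block (0.0488) and in both FPKM fits (0.0374 and 0.0294). Neither the Fanconi list nor this list passed with an estimated correlation in the fit of all libraries. PRKDC, the catalytic subunit of DNA-PK, stood at 420 ± 79.4 CPM in KO2 against 719 ± 183 in NC (log2 −0.78, SE 0.28, adjusted p = 0.150) and at 640 ± 91.9 in KO1 against 772 ± 188 (log2 −0.27). The Ku subunit genes stood at 353 ± 146 CPM in KO2 against 417 ± 132 (XRCC5) and 462 ± 137 against 503 ± 159 (XRCC6). In KO1 they were at 406 ± 64.1 against 454 ± 145 and 435 ± 30.5 against 536 ± 170. The 13 mitochondrially encoded genes all had a negative log2 fold change (median −0.85; list adjusted p = 9.37e-04, adjusted p = 0.633 with an estimated correlation), 0 passed over all genes and 1 adjusted over the list alone, MT-ATP8 at −1.47. The mitochondrial share of counts was 5.33%, 4.92% and 5.85% in KO2 replicates 1 to 3 and 5.65%, 7.89% and 7.74% in NC. NC replicate 1 thus lay within the KO2 range.

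**Figure D3:**
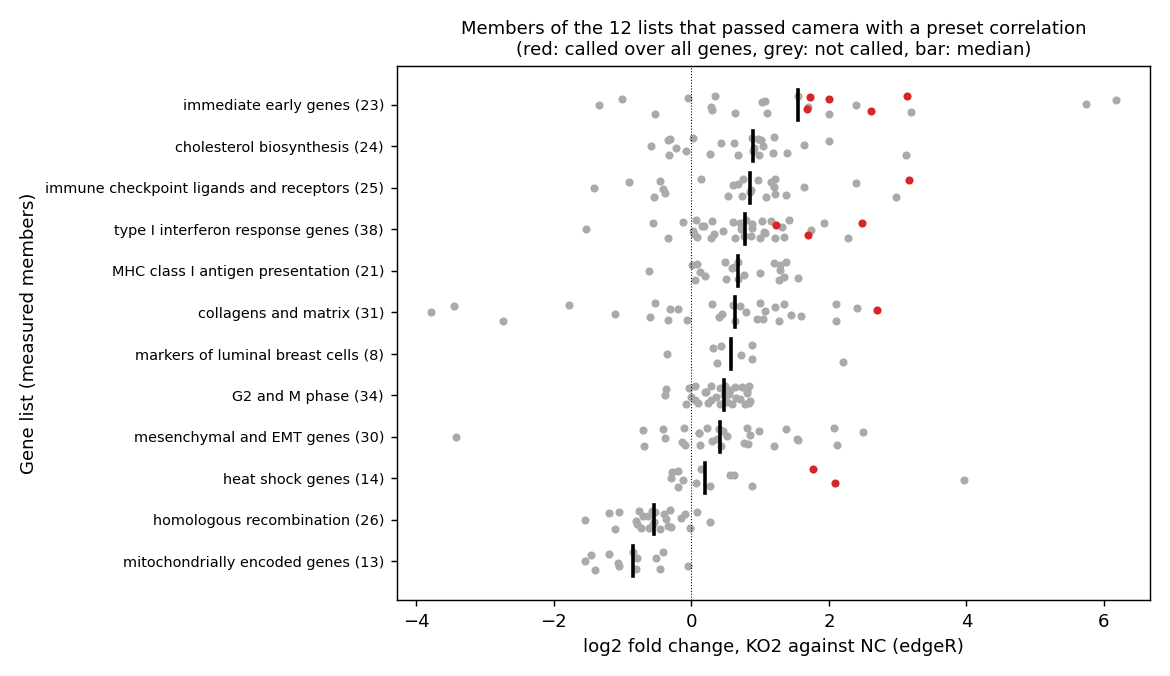
Log2 fold change of KO2 against NC (x axis) for each measured member of the 12 lists that camera called with the preset correlation, 1 point per gene, red where the gene itself passed and grey where it did not. Immediate early genes had the highest median, 1.55, and mitochondrially encoded genes the lowest, −0.85.

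Lists that did not pass in KO2 still held called genes. The 16 Wnt/beta-catenin target genes (median 0.10, 0 called, adjusted p = 0.210) passed with the fry test alone (0.0136). Of 34 Wnt receptor, ligand and polarity genes (list adjusted p = 0.0822), the ligand WNT9A (2.12) and the receptor FZD7 (1.55) rose and the polarity cadherin CELSR3 fell by 1.61 (3 higher and 1 lower adjusted over the list alone), and FZD2 was at 1.30 without passing. The epithelial genes CD24 (2.21) and DSP (3.60), the p53 target PMAIP1 (1.78) and the leukocyte marker PTPRC (4.84; 8.58 to 12.9 CPM in KO2 against 0.182 to 0.468 in NC) rose, and ANGPTL4, a lipoprotein lipase inhibitor induced by hypoxia, fell by 4.76. The leukocyte list as a whole did not pass, with 6 of its 22 genes measured and 1 called (adjusted p = 0.527).

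Genes on part of chromosome 3 were lower together in KO2, a region chosen after the data were seen. Over 270 genes in the first 80 Mb the median log2 fold change was −0.64 (quartiles −0.996 and −0.26), 87.8% were lower, 14 were called lower and 0 higher. Chromosome 13 had a median of −0.50 over 177 genes, and 160 to 180 Mb of chromosome 1 a median of 0.57 over 80 genes, 8 of them called higher. In KO1 against NC the same regions had medians of −0.24, −0.24 and −0.20, beside −0.0021 for the genes outside the chromosome 3 and 13 regions. Those include chromosome 6, which carries PTK7, with a median over 526 genes of −0.21 in KO1 and 0.18 in KO2. In the first table the chromosome 3 region stood at −0.117 in NC replicate 1, −0.127 to −0.0557 in KO1, and 0.198 and 0.233 in NC replicates 2 and 3. Of the 26 recombination genes, 1 lay on chromosome 13 or in the first 80 Mb of chromosome 3, and without it the median of the list was −0.54.

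**Figure D4:**
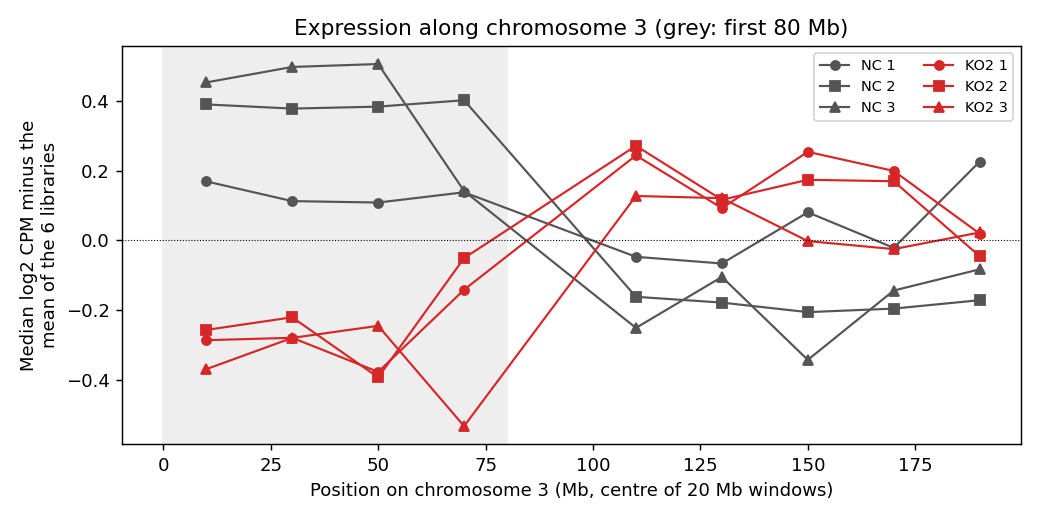
Median log2 CPM of the genes in 20 Mb windows along chromosome 3 (x axis, Mb), minus the mean of the 6 libraries, with 1 line per library of the second table (NC black, KO2 red) and the first 80 Mb in grey. In the grey part each KO2 library lay below each NC library in every window, and 87.8% of 270 genes had a lower mean in KO2 than in NC.

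With all libraries, 0 genes were called in both knockouts, since edgeR called 0 genes in KO1. DESeq2 with all libraries called 2 genes higher and 18 lower in both, and edgeR without a filter on low counts 28 higher and 127 lower, with 37 in opposite directions. Without the library labelled NC replicate 1, 26 genes were higher in both knockouts against 0.949 for independent lists, 66 were lower in both against 2.64, and 3 went in opposite directions. Both comparisons share the same NC libraries. Simulated unchanged knockouts against those NC libraries gave a mean of 0.15 shared genes. The simulation gave all libraries the same mean for each gene, so it held no difference of NC replicates 2 and 3 from the library left out. It cannot tell such a difference from an effect common to both guides. The covariance of the log2 fold changes across genes was 0.457 against 0.143 simulated, while with all libraries it was 0.112 against 0.112. With all libraries the simulated spread was taken from fits that include the departure of NC replicate 1. The equal values therefore do not show that a common effect is absent. The Pearson correlation across genes, which are not independent, was below the simulated value, at 0.486 against 0.603 without that library and 0.239 against 0.498 with it. So was the share of genes with the same sign, at 63.1% against 70.4% and 57.5% against 66.6%.

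IDO1, which degrades tryptophan and dampens T cells, rose by 5.14 on the log2 scale in KO1 and by 5.87 in KO2 without that library, at 37.0 to 73.6 CPM in KO1 and 1.77 and 1.07 in NC replicates 2 and 3. The transporter gene ABCA5 rose by 3.52 and 3.82, B4GALNT3 by 3.24 and 4.43 and the semaphorin SEMA3D by 4.24 and 6.79. The library left out held 29.2, 16.6, 8.18 and 3.95 CPM of these genes. ADAM23 (6.62 and 4.60), the calcium-binding CALB2 (5.10 and 4.504) and ALDH1L1 (5.17 and 4.27), an enzyme of folate metabolism, also rose, and the library left out held 50.3, 42.3 and 56.4 CPM of them, above the NC replicates 2 and 3 and above all KO1 libraries; with all libraries their KO2 values were −0.87, −0.48 and −0.06. JAKMIP3 had ratios of 56.1 (18.96 to 274) and 31.0 (10.4 to 152), with 10.9 CPM in the library left out and a KO2 value of −0.22 with all libraries. PCYT1B was at least 13.5-fold higher in KO1 and 102-fold in KO2. CHRNA1 had ratios of 103 (18.2 to 4093) and 127 (22.6 to 5052), CDH19 of 62.5 (10.9 to 2496) and 142 (25.3 to 5651) and TSPAN8 of 14.2 (4.63 to 70.9) and 48.1 (16.3 to 235). The library left out held 1.76, 1.199, 3.88 and 0.212 CPM of these genes.

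Connexin 26, GJB2, had a log2 fold change of −7.89 in KO1 and −4.69 in KO2, from 137 and 67.7 CPM in NC replicates 2 and 3 to at most 0.508 CPM in KO1, with the library left out at 0.494. Keratins and a metallothionein fell with it: KRT14 (at least 269-fold in KO1, a ratio of 470 with interval 130 to 3891 in KO2), KRT6A (−5.79 in KO1, at least 99.1-fold in KO2) and MT1E (at least 48.1-fold and 65.2-fold). PLCH2 fell by 6.29 and 6.07. XYLT1 was at least 108-fold lower in KO1 and at −4.88 in KO2, and CADM3 was at −4.79 in KO1 with a ratio of 416 (74.0 to 16472) in KO2. DAAM2, a formin of Wnt signalling, had a ratio of 129 (22.6 to 5158) in KO1 and a log2 fold change of −4.71 in KO2. PLA2G4E had a ratio of 109 (29.6 to 906) and was at least 83.9-fold lower in KO2, ZFP30 a ratio of 125 (21.9 to 4997) and at least 51.1-fold. SHISA2 had ratios of 95.2 (16.5 to 3815) and 115 (20.1 to 4612), and the ectodysplasin receptor EDA2R of 47.6 (12.7 to 401) and 109 (18.99 to 4372). The library left out was at 0 in both tables for KRT14, KRT6A, MT1E, XYLT1, DAAM2, ZFP30, SHISA2 and EDA2R, and in the second table at 0.191 CPM for PLCH2, 0.382 for PLA2G4E and 2.16 for CADM3. KO2 lay above it for GJB2 (3.51 to 3.85 CPM against 0.446), XYLT1 (0.192 to 0.331 against 0) and DAAM2 (0.0583 to 0.132 against 0). In KO2 with all libraries, CADM3 was called (adjusted p = 0.0255), GJB2 was not (−4.11, adjusted p = 0.129), and the other genes of this paragraph did not pass the count filter.

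**Figure D5:**
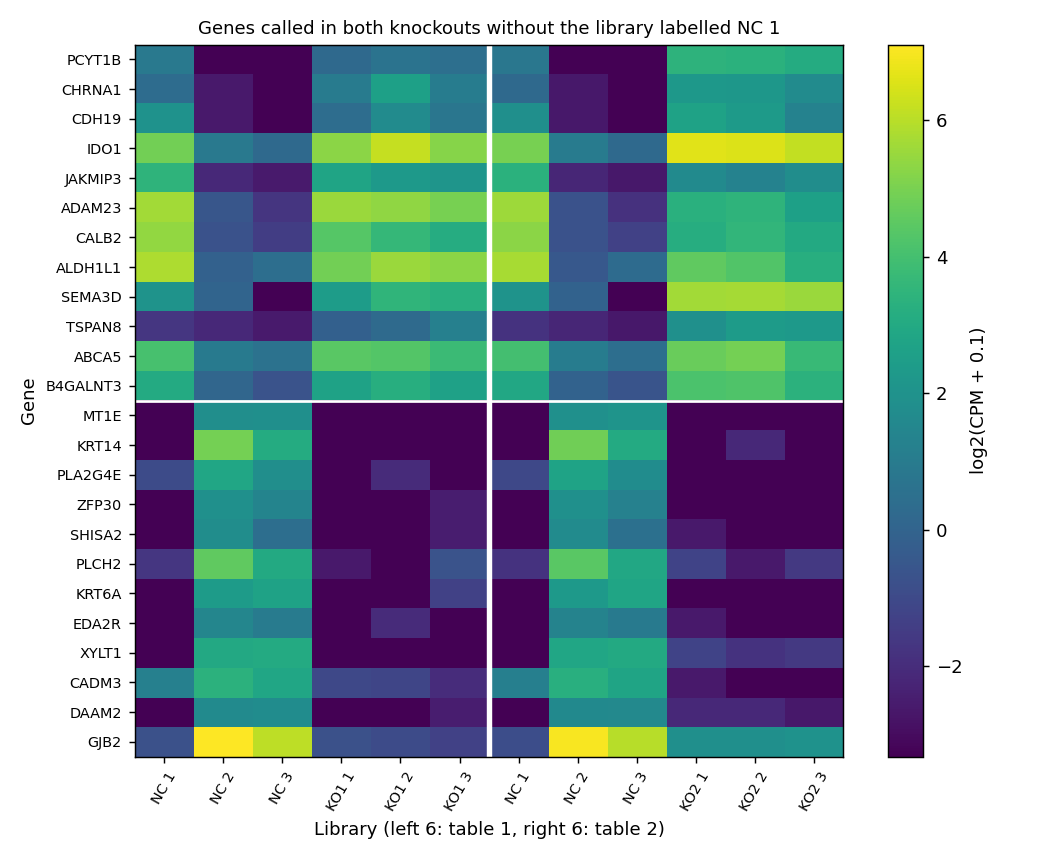
Level as log2(CPM + 0.1) of the 24 genes named as changed in both knockouts without the library labelled NC replicate 1, 1 row per gene and 1 column per library of each table. The upper 12 genes rose and the lower 12 fell; GJB2 stood at 0.494 CPM in NC replicate 1 of the first table, beside KO1.

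KO2 against KO1 was tested after the data were seen, across the 2 tables, so that the KO1 and KO2 levels come from separate runs of the authors' processing. edgeR called 1544 of 14519 genes, 770 higher and 774 lower in KO2. The actin-bundling gene LCP1 stood at 155 ± 6.63 CPM in KO2 and 1.66 ± 1.26 in KO1 (log2 6.62, SE 0.52), the neuropeptide precursor GAL was at least 66.3-fold higher in KO2, and CORO2B had a ratio of 130 (23.002 to 5171). RPS6KA2, a MAP kinase-activated kinase, was higher by 6.59, and FOS by 6.56, with FOS at 715 CPM in KO2 replicate 3 and 28.2 and 25.8 in KO2 replicates 1 and 2. Without KO2 replicate 3 the FOS difference was 3.35 (adjusted p = 5.03e-04), and its call ended without KO1 replicate 1 (0.118), 2 (0.112) or 3 (0.123). Without KO1 replicate 3 the calls of CORO2B (0.0502) and RPS6KA2 (0.0573) ended, and without KO1 replicate 2 RPS6KA2 was at 10.49. NAA11 (at least 346-fold), ACSS3 (166-fold), DCAF8L2 (118-fold) and LINC00960 (63.9-fold) were lower in KO2, and EPB41L3 had a ratio of 1094 (196 to 43248). NC replicates 2 and 3 of the second table held little NAA11 (0.641 and 0.364 CPM), ACSS3 (0.117 and 0.121) or DCAF8L2 (0.466 and 0.182). NC replicate 1 held 16.8, 14.8 and 6.43 CPM of them. LCP1 (85.1 and 153 CPM), GAL (1.51 and 6.43) and CORO2B (7.46 and 7.40) were present in NC replicates 2 and 3, against 0.446, 0 and 0 in NC replicate 1. The differences of these genes are therefore not changes of KO2 from all NC libraries. PTK7 itself was higher in KO2 than in KO1 by 1.72 (SE 0.32, adjusted p = 0.0160), in 3 of 3 libraries against 3. The count was 486, 392 and 324 without KO1 replicates 1, 2 and 3, 467 and 470 without KO2 replicates 1 and 2, and 6663 without KO2 replicate 3.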

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

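Every test in this part was chosen after the result was seen, except those of GC content and transcript length on chromosome 3, of the other splits of KO2 against KO1 and of a batch term for the naming style. Groups of 3 libraries were too small for a test of single outlying samples.

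The results below stood out because the level in KO2 differed from that in KO1 by a direct test of KO2 against KO1 across both tables (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Guide, table and, if each group is 1 monoclonal line, clone differ together in this test and cannot be told apart. The test called 1544 genes, and of the 10 splits of the 6 libraries into 3 and 3, the real one was the 1 with this many calls and the highest other had 0. With 10 splits there are too few for a share under 0.05. For KO2 against NC the real split was likewise 1 of the 10, with 218 calls against at most 6. For KO1 against NC all 10 splits gave as many as the real count of 0, the highest other being 0. A real count of 0 fixes that in advance, so the splits decide nothing for KO1.

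PTK7 was higher in KO2 than in KO1 by 1.72 on the log2 scale. The lists were not tested between KO2 and KO1, so the values below describe single genes. Of the interferon, MHC class I and checkpoint genes named above, those that passed were ISG15, higher by 1.25, HERC5 by 2.31, IRF7 by 1.44, TAP1 by 1.30, TNFSF9 by 4.29, CD70 by 3.87, CD276 by 1.22 and ULBP2 by 1.52. IFIH1 (0.74) and TAPBP (1.15) did not pass, and HLA-B and HLA-C were not among the genes tested. JUN was higher by 1.85, ATF3 by 2.51, JUND by 1.88, DUSP1 by 3.72, FOS by 6.56 (3.35 without KO2 replicate 3), DNAJB1 by 1.99 and PMAIP1 by 1.79. Among named Wnt genes the differences were 3.58 for WNT7B, 3.84 for WNT5B, 1.49 for WNT9A, 1.30 for FZD7, 1.67 for FZD2 and −1.01 for CELSR3. Named matrix, mesenchymal and epithelial genes differed by 1.85 for COL4A1, 3.16 for FBN1, 2.04 for SPARC, 1.32 for MMP2, 4.13 for MMP14, 5.46 for DSP and 3.19 for KRT17. Named cholesterol genes differed by 3.48 for INSIG1, 1.88 for MSMO1 and 1.60 for STARD4.

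Further differences were 4.37 for CSF3, −2.67 for CXCL3, −3.84 for ANGPTL4, −1.56 for MT-ATP8, 1.04 for TOP2A, −2.07 for ADAM23, 2.60 for SEMA3D, 3.20 for GJB2, −3.53 for CHRNA7, −3.05 for CNBD1, 3.12 for PCDHB14, −2.70 for ZNF525, −2.57 for ZNF160, −2.12 for ZNF195, 6.62 for LCP1 and 6.59 for RPS6KA2. For genes with 0 to 3 counts in a group the fitted differences depend on the prior count and are no bounds: 9.24 for GAL, 6.79 for CORO2B, −9.44 for EPB41L3, −8.79 for LINC00960, −11.22 for NAA11, −10.16 for ACSS3 and −9.69 for DCAF8L2. Their floors and ratios were at least 66.3-fold for GAL, 130 (23.002 to 5171) for CORO2B, 1094 (196 to 43248) for EPB41L3, and at least 63.9-fold, 346-fold, 166-fold and 118-fold for the others.

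The first pattern was that the library labelled NC replicate 1 lay with KO1. A swap with a KO1 library was argued against by PTK7, since the highest KO1 library held 22.4% of the lower of NC replicates 2 and 3. A batch shared by the first libraries of both groups was argued against by the slope of their deviations, 0.177 (jackknife SE 0.0119) where a batch as the whole cause predicts a slope near 1, but the slope was above 0, these libraries were the closest pair of the first table over chromosome windows (0.0770, against 0.0983 or more for the others) and alone carry another style of column name, so a smaller shared part stays open; a batch term for that style gave 0 calls by edgeR (971 at an unadjusted p under 0.05). A single wrong label, a knockout library labelled NC, stays open. Over chromosome windows the largest distance of this library to a KO1 library was 0.736 of the smallest to another NC library. That ratio measures again the nearness to KO1 that defined the pattern, so it cannot tell a wrong label from other causes. Drift or clonal differences between NC cultures stay open, as the labels do not describe the cultures, and no biological explanation was tested.

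The second pattern was that KO2 replicate 3 stood apart from KO2 replicates 1 and 2. An NC library with a wrong label was argued against by chromosome windows, where its largest distance to another KO2 library was 0.624 of its smallest to an NC library, and by EPB41L3 with 0 counts against 28.5 to 42.9 CPM in NC, although over genes it lay nearer to NC replicates 2 and 3 (chi-square over degrees of freedom 93.1 and 86.3) than to KO2 replicates 1 and 2 (173 and 176). NC cells mixed in at 0.553, the median share that its level over 1754 genes would need, were argued against by 13.3% of 150 genes silent in KO2 replicates 1 and 2, which lay under the counting range of even 0.5 of that share, although the median share of the same 150 genes was 0.588. A smaller admixture was not decided by a test over 12 pairs of cutoffs, in which 10.7% to 100% of such genes stayed under 0.05 of the lowest NC level. With silence set at 0.1 CPM and NC at 2 CPM or more, 6 of 7 genes stayed under it. EPB41L3 at 0 counts leaves room for a small share only, but this rests on few genes, most of them low in NC. These tests were rewritten after an earlier version, 2 genes with a median share of 0.623 (EPB41L3, and LCMT2 at 13.8 CPM), had been seen. A different culture state or subclone stays open and was not tested.

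The third pattern was the lower expression over the first 80 Mb of chromosome 3 in KO2. GC content and transcript length were argued against, since the region kept 100.5% of its median after a fit on both. A lower copy number of the region in the KO2 cells cannot be told apart from other causes: 87.8% of its genes were lower in KO2, but this rests on the genes that showed the pattern, and the region was also lower in KO1 (median −0.24), where NC replicate 1 stood with KO1. A difference among the NC libraries and regional regulation stay open, and no DNA data were at hand.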

How the results depend on the processing

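Alternatives added after the data were seen were voom, DESeq2 size factors or no TMM in edgeR, the fits that leave out libraries of both groups or sum KO2 replicates 1 and 2, and all of KO2 against KO1. Over 112 pairs of a named gene and a comparison, 1758 of 2463 alternatives kept direction and side of the threshold, 345 kept direction and were no longer called, 286 were newly called and 74 turned direction. Each was set against the fit with all libraries, in which edgeR called 0 genes in KO1. An unchanged KO1 gene is therefore one that stayed not called. The tally does not measure how well the genes reported without the library labelled NC replicate 1 held. A fit of all 9 libraries together, a batch term for KO2 and FPKM alternatives for KO2 against KO1 were not run. For KO1 the replicate block changed no gene call over all genes, and no list call by camera beyond those named above. Depth limits genes near 0 counts, where only floors or counting intervals can be given. Where no cause is named, the cause was not tested.

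In KO1 against NC the count of 0 became 67 with DESeq2, 411 without a filter on low counts, 1328 without replicate 1 of both groups and with a block, and 0 to 581 with 1 library left out. The 218 calls of KO2 became 979 with the replicate block, 1999 with DESeq2, 1953 without a filter, 6 at a mean FPKM of at least 5, 7233 with voom and sample weights, 1 with KO2 replicates 1 and 2 summed, 6855 without KO2 replicate 3 and NC replicate 1, 1 at an adjusted p under 0.01 and 1 to 3498 with 1 library left out. limma-trend gave 115 at log2(FPKM + 1), 102 and 39 with pseudocounts of 0.5 and 0.1, 0 without a filter (4729 at an unadjusted p under 0.05), 42 at a mean FPKM of at least 5, 86 with TPM, 118 with TMM, 113 with median centring, 114 with quantile normalization, 104 robust and 6295 with array weights. KO2 against KO1 gave 3035 with DESeq2, 298 at an adjusted p under 0.01 and 324 to 6663 with 1 library left out. Genes called in both knockouts numbered 20 with DESeq2, 155 without a filter, 285 without NC replicate 1 and KO2 replicate 3, and 0 to 92 with 1 library left out. Lists called in KO1 went from 6 to 0 with an estimated correlation and 0 with fry (5 to 9 with 1 library left out), and in KO2 from 12 to 0 and 4 (11 to 16).

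PTK7 in KO1 passed with DESeq2 (−2.27), without a filter (−2.27) and without replicate 1 of both groups (−2.54), and ran from −2.74 to −1.78 with 1 library left out. In KO2 it was −0.82 without KO2 replicate 3 and NC replicate 1, and −1.04 to −0.08 with 1 library left out.

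PRKDC in KO1 turned to 0.0044 with array weights, and XRCC6 in KO2 to 0.0087 with KO2 replicates 1 and 2 summed. With 1 library left out, XRCC5 ran from −0.36 to 0.0876 in KO1 and from −0.63 to 0.0144 in KO2, XRCC6 in KO2 from −0.38 to 0.0736, and JAKMIP3 in KO1 from −0.0679 to 5.62.

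The genes that NC replicate 1 held at a high level turned from negative to positive under several fits. CALB2 in KO1 gave 2.45 with the block, 2.49 with a batch term for naming style, 3.81 with voom, 4.73 without replicate 1 of both groups and −0.63 to 5.10 with 1 library left out. With limma-trend it was 1.33 (also without a filter, at FPKM of at least 5, robust, median centred), 1.75 and 2.48 with the smaller pseudocounts, 1.99 with TPM, 1.34 with TMM, 1.23 with quantiles and 2.20 with array weights. In KO2 the block gave 2.21 for JAKMIP3, 2.30 for ADAM23, 2.43 for CALB2 and 2.18 for ALDH1L1. In the same order, voom gave 3.60, 3.77, 3.61 and 3.83, leaving out 1 library gave from −0.79 to 4.93, from −1.44 to 4.60, from −1.05 to 4.504 and from −0.64 to 4.27 (the highest without NC replicate 1), and leaving out KO2 replicate 3 as well gave 4.80, 4.81, 4.61 and 4.57. For ADAM23, CALB2 and ALDH1L1 in KO2, limma-trend gave 0.0538, 0.85 and 0.24 (also robust or without a filter, and for CALB2 at FPKM of at least 5), 0.33, 1.23 and 0.51 at a pseudocount of 0.5, 1.198, 1.88 and 1.31 at 0.1, 0.67, 1.58 and 0.83 with TPM, 0.13, 0.95 and 0.32 with TMM, 0.17, 0.97 and 0.36 with median centring, 0.23, 0.98 and 0.43 with quantiles, and 0.84, 1.86 and 0.95 with array weights.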

Other observations

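The tests in this part were chosen after the KO2 calls were seen. Both families were picked from those same calls, so the p-values do not measure how unusual the families are. Protein-coding zinc finger genes were over-represented among the genes that fell in KO2. Of 390 tested protein-coding genes with a ZNF symbol, 16 fell against 2.73 at the rate of all protein-coding genes (Fisher's exact test, adjusted p = 8.10e-08), 0 rose, and 11 of the 16 lie on chromosome 19. The test treats genes as independent, which genes of 1 chromosome need not be. By symbol alone 19 of 428 fell against 3.13 (adjusted p = 2.16e-09), which adds the antisense transcript ZNF433-AS1 and the pseudogenes ZNF37BP and ZNF731P. ZNF525 stood at 0.897 to 1.53 CPM in KO2 against 6.94 to 10.3 in NC (log2 −2.93), ZNF160 had a log2 fold change of −2.57 and ZNF195 of −1.71. These were chosen after their values were seen, among members with more than 3 counts in KO2. In KO1 without the library labelled NC replicate 1, 6 of 408 protein-coding genes fell against 8.58, with an adjusted p of 1.

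Clustered protocadherins, adhesion genes of chromosome 5, moved the other way in KO2. Of 25 tested, 5 rose against 0.158 at the rate of all genes (Fisher's exact test, adjusted p = 1.73e-06), and 0 fell, with a median log2 fold change of 1.83. PCDHB14 stood at 13.3 to 17.7 CPM in KO2 against 0.913 to 1.93 in NC (log2 3.59), PCDHGA9 rose by 3.60 and PCDHB12 by 3.88. In KO1 without the library labelled NC replicate 1, 3 of 26 rose against 0.424 (adjusted p = 0.0226). Neighbouring cluster members share sequence and control regions, so they are not independent genes.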
